A study of Shewanella oneidensis with 8 samples.

How the data were processed

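RNA was measured in 8 samples of *Shewanella oneidensis* MR-1, a Gram-negative bacterium that respires oxygen as well as metals and other electron acceptors. Per the labels, 4 samples were wild type and 4 carried a deletion of cpdA, the gene of a phosphodiesterase that breaks down cyclic AMP. Per the labels' protocols, cells grew with oxygen in minimal medium with lactate and were collected in logarithmic phase, and total RNA was turned into Cy3-labelled cRNA. Each sample was hybridised to its own 1-colour Agilent array. The design text calls the 4 samples of each strain biological replicates. The labels do not say how or on which days the cultures were started.

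Per the file headers, the deposited scanner intensities came from Agilent Feature Extraction 11.5.1.1, whose processed signal is the spot brightness after background subtraction and spatial detrending, with no scaling between arrays. The submitters' processing notes name Feature Extraction 8.1 instead, and the reason for the difference is not given in the sources used here. The authors also deposited a value table on a log2 scale. Set against the scanner values, each of its columns correlated at 0.999996 or above with log2 signal minus the array's 75th percentile, centred on the median of each probe over the 8 arrays. The column medians of the authors' log2 table lay between -0.011 and 0.010, so its scale, centring and direction could be read from the data.

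Each array held 13915 spots, of which 13379 were not controls and stood for 4769 genes. There were 3 probes for 4186 genes, 2 for 238 genes and 1 for 345 genes. The main values were log2 of the processed signal minus the 75th percentile of the non-control spots of the same array. The 23 non-control spots marked as non-uniform or population outliers were left out on their array. A probe was kept if its spot was well above background on at least 4 of the 8 arrays, which kept 13301 probes and left out 78. A gene's value on an array was the mean of its kept probes, with an additive probe and array fit where a spot was missing, so that probes of a gene that disagree are averaged. This left 4749 genes to test and 20 without a kept probe. No spot was saturated. The number of arrays, 4 per strain, limits the precision of every value.

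The array files name genes by locus tag. Genes were taken as neighbours by the order of these locus tags alone. A RefSeq gene table of assembly ASM14616v2 was used only for symbols and their synonyms. It held 4137 of the 4769 locus tags, and 1220 of these had a symbol. The other 632 keep the name in the array files. No coordinates are given, because the build behind the array design is not given in the sources used here. A few symbols belong to more than 1 locus, and the locus tag is then added.

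Strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 8 arrays with no covariate. Benjamini-Hochberg adjustment ran over the 4749 genes, and a gene was called at an adjusted p under 0.05. All adjusted p-values of single genes come from this limma fit. Changes are the deletion minus the wild type on the log2 scale, with the standard error (SE) of the fit. Levels are log2 values relative to the array's 75th percentile, with the SD over 4 arrays. Because each array is scaled to its own 75th percentile, changes are relative to the rest of the transcriptome. The median change of all genes was 0.03.

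Gene lists were written before the data were examined, from textbook pathways of amino acid, energy and cyclic AMP metabolism, with ribosomal proteins as a list related to growth rate and 3 prophage regions. Of 32 lists, 8 had been defined by product names, which the gene table does not hold. These were restated by symbol and locus after the data files were opened and before any test: ribosomal proteins, flagella and chemotaxis, aminoacyl-tRNA synthetases, peptidases and proteases, amino acid transport, iron acquisition and cyclic dinucleotide signalling. The transposase list matched no gene and was not tested. The 31 other lists were tested with camera from limma with a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives. Camera compares a list with the other genes, while fry tests it against no change. For each list the members past the single-gene test were counted, over all genes tested and adjusted over the list alone.

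Genes are named by a rule fixed before the data were examined. It takes cpdA, the genes of cyclic AMP signalling and the neighbours of cpdA whatever their values. It adds the 12 largest rises and the 12 largest falls among called genes with a symbol whose 4 deletion arrays all lay on one side of all 4 wild-type arrays. It then takes up to 4 called members of each list with the largest change. Other names are said to have been chosen after their values were seen.

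For a probe not well above background on all 4 deletion arrays a fold is a bound. It sets the mean of the bright strain against the mean, over the arrays of the dim strain, of the lowest signal among probes well above background on that array, or of the probe's own signal where that is higher.

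The steps were tested on simulated data for the comparison of the deletion with the wild type, with 4749 genes. At a simulated log2 change of 0.25 the fit recovered 27 of 50 genes, at 0.5 it recovered 49 of 50, and at 1 and at 2 it recovered 50 of 50. Of the 4549 unchanged genes, 6 were called. Both lists shifted by 0.5 were called, and 0 of 28 unchanged lists. The simulated genes varied independently of each other, and only the 2 shifted lists were changed. The error rate of camera where genes of a list vary together was therefore not tested.

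The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, no filter on dim probes, a filter asking for all 8 arrays, the brightest probe of each gene, leaving out saturated probes, the authors' value table, array weights, an intensity trend with a robust prior, the scan run as a random block, the replicate number as a block, and leaving out each array in turn. Normexp had been planned on mean spot signals. The scanner files hold median spot signals, and these were used with the median background.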

Results

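Transcript levels of *Shewanella oneidensis* MR-1 lacking cpdA were compared with those of the wild type, with 4 arrays per strain. The title of the series ties CpdA to amino acid metabolism, and the comparison asks which genes, those of amino acid metabolism first, differ when cpdA is missing. Between 97.8% and 99.6% of the 13379 non-control spots of an array were well above background. The 75th percentile of the processed signal lay between 2806 and 4630, with deletion replicate 1 the brightest array and the other 7 at 3487 or below. Correlations of gene values across genes ran from 0.9977 to 0.9987 between wild-type arrays, from 0.9942 to 0.9981 between deletion arrays and from 0.941 to 0.951 between strains. Genes are not independent replicates in these values. The arrays fall into 3 scan runs: all 4 wild-type arrays in run 1, deletion replicates 1 to 3 in run 2 and deletion replicate 4 in run 3. No run holds both strains, so no value within a run can be given. The file headers give 1 slide identifier for all 8 arrays, and whether this is an error is not given in the sources used here.

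The deleted gene was checked first. CpdA is the phosphodiesterase that breaks down cyclic AMP. The 3 probes of cpdA (SO_3901) gave processed signals of 6297 to 11769 on the wild-type arrays and of 3.34 to 57.1 on the deletion arrays. On all 4 deletion arrays 2 of the probes were not well above background, and their signals were at least 339-fold and at least 397-fold lower than in the wild type. The third was well above background on 1 deletion array, replicate 2. The fitted log2 change of cpdA was -10.09 (SE 0.35, adjusted p = 2.66e-09), and it depends on signals near the background. With normexp background correction it was -6.85. An exact two-sided permutation test on the mean of the 3 probes gave p = 0.0286, the smallest that 4 against 4 arrays can give. Which part of the gene was removed is not given in the sources used here.

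Other genes of cyclic AMP signalling changed by less. The SO_4312 transcript, listed as the adenylate cyclase gene cyaA, fell by 1.13 on the log2 scale (SE 0.05, adjusted p = 3.25e-08), which is 2.18-fold. SO_1329, listed as the adenylate cyclase gene cyaC, fell by 0.21 (adjusted p = 0.00851), and cyaB rose by 0.52 (adjusted p = 1.42e-05). The change of crp, the cyclic AMP receptor protein, was -0.10 (SE 0.05, adjusted p = 0.0952). It passed the test with quantile normalization (-0.21), with array weights (-0.13) and without deletion replicate 4 (-0.12). As a list of 5, with cpdA itself included, these genes were not called by camera (adjusted p = 0.154), with 1 higher, 3 lower and a median of -0.21.

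Of the 10 genes next to cpdA, 6 were higher in the deletion and 0 lower, over all genes and adjusted over the list alone. SO_3900, the gene beside cpdA, rose 2.52-fold (log2 1.34, SE 0.05, adjusted p = 2.55e-09). The topoisomerase IV genes parE and parC rose by 0.72 and 0.46, SO_3896 by 0.27, nudF by 0.20 and SO_3905 by 0.14. SO_3896 no longer passed with quantile normalization (0.10, adjusted p = 0.0973), nor did SO_3905 with quantile normalization (0.07, adjusted p = 0.222) or the brightest probe (0.13, adjusted p = 0.0806). SO_3905 did not pass either without wild-type replicate 1 (adjusted p = 0.0587), 2 (0.0733) or 4 (0.067), or without deletion replicate 4 (0.0511). The values of SO_3898 (0.37), SO_3902 (0.17), tolC (0.08) and SO_3906 (0.07) did not pass. SO_3898 passed with the brightest probe (0.67, adjusted p = 1.12e-05), with array weights (0.52) and without deletion replicate 3 (0.63). SO_3902 passed with the brightest probe (0.25, adjusted p = 0.00618), with array weights (0.13) and without deletion replicate 4 (0.23), and SO_3906 with normexp (0.09), median scaling (0.10) and array weights (0.07). The neighbours as a list were called higher (mean log2 0.38, adjusted p = 0.043), with adjusted p = 0.377 with an estimated correlation. That call was lost with quantile normalization (adjusted p = 0.124), and without wild-type replicate 1 (0.0517), wild-type replicate 4 (0.0656) or deletion replicate 1 (0.0587).

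Across the genome, 3343 of 4749 genes differed between the strains (70.4%), 1800 higher and 1543 lower in the deletion. Most of these changes were small: 2366 of the 3343 were under 1.5-fold and the median size was 0.40 on the log2 scale. At least 2-fold, 174 genes were higher and 199 lower, and at least 4-fold, 29 were higher and 86 lower. The largest changes were falls. All 4 deletion arrays lay on one side of all 4 wild-type arrays for 3127 genes, where chance gives 2.86% of genes. The 373 genes changed at least 2-fold were all among them.

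**Figure D1:**
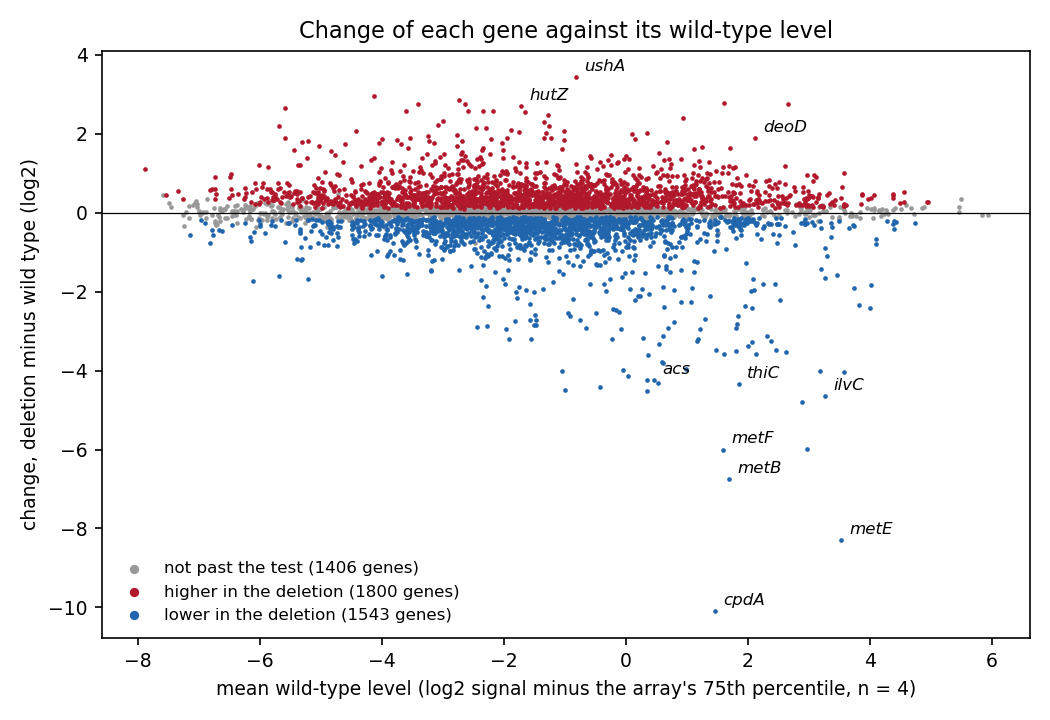
Each point is 1 of the 4749 genes. The horizontal axis gives its mean log2 level over the 4 wild-type arrays, relative to each array's 75th percentile, and the vertical axis the log2 change in the cpdA deletion. Red and blue points passed the test (1800 higher, 1543 lower), and the lowest points are cpdA at -10.09 and metE at -8.30; values of cpdA in the deletion lie near the background.

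The largest falls after cpdA were in methionine synthesis. The metE transcript, of the cobalamin-independent methionine synthase, was 315-fold lower (log2 -8.30, SE 0.08, adjusted p = 1.58e-13), with mean levels of 3.53 ± 0.05 in the wild type and -4.77 ± 0.16 in the deletion (SD, n = 4 arrays each). The metB gene, of cystathionine gamma-synthase, was 108-fold lower and metF, of methylenetetrahydrofolate reductase, 64.2-fold lower. With normexp these 3 folds were 197, 63.7 and 42.2. The cobalamin-dependent synthase gene metH was 17.8-fold lower (adjusted p = 1.39e-10). Of the 22 measured genes for methionine, cysteine and sulfate assimilation, 20 were lower, 0 higher and 2 did not pass, over all genes and adjusted over the list alone. The list was called lower (mean log2 -2.72, adjusted p = 5.08e-14; adjusted p = 0.0998 with an estimated correlation).

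Branched-chain amino acid synthesis fell as a whole: 11 of 11 measured genes were lower, with a mean log2 change of -3.07 (adjusted p = 3.47e-08; adjusted p = 0.203 with an estimated correlation). The ilvC gene, of ketol-acid reductoisomerase, was 24.97-fold lower (log2 -4.64, SE 0.04), ilvG and ilvM, of acetolactate synthase, 22.7-fold and 18.8-fold lower, and ilvD, of dihydroxy-acid dehydratase, 15.9-fold lower. All 8 histidine synthesis genes were lower too, with a mean of -2.57 (adjusted p = 3.45e-06; adjusted p = 0.203 with an estimated correlation). Among them hisC was 9.18-fold lower, hisB 7.73-fold, hisD 7.31-fold and hisH 7.21-fold. With normexp the folds of hisC, hisB and hisD were 5.78, 4.81 and 4.43. Deletion replicate 1 had the lowest value of hisD (-5.39 against a mean of -5.07 on the other 3 deletion arrays) and of hisH (-4.78 against -4.17).

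In threonine and lysine synthesis, the threonine genes thrB, thrA and thrC were 12.01-fold, 11.1-fold and 9.57-fold lower, and the aspartokinase gene lysC fell by 0.95 on the log2 scale. Of the 11 genes of this list 8 were lower and 2 higher, or 8 and 3 adjusted over the list alone, and the list was called lower (mean -1.13, adjusted p = 0.0214; adjusted p = 0.345 with an estimated correlation). Aromatic amino acid synthesis had 10 of 14 genes lower and 2 higher (mean -1.15, adjusted p = 0.00355; adjusted p = 0.249 with an estimated correlation). The tyrA gene, of tyrosine synthesis, was 13.8-fold lower, and trpD, trpCF and trpB, of tryptophan synthesis, were 6.66-fold, 5.46-fold and 4.34-fold lower. In the group of serine, glycine, proline, glutamate and asparagine, 10 of 13 genes were lower and 3 higher (mean -1.02, adjusted p = 0.00499; adjusted p = 0.137 with an estimated correlation). Here the asparagine synthetase gene asnB (SO_2767) was 9.59-fold lower, gltB 4.04-fold, serA 3.78-fold and glyA 3.01-fold. Arginine synthesis changed least, with 5 of 7 genes lower and 0 higher (mean -0.43, adjusted p = 0.0312; adjusted p = 0.269 with an estimated correlation), led by argB at 2.13-fold and argC at 1.72-fold lower, with carA (-0.43) and argA (-0.38).

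Taken as 1 list, 72 of the 86 measured amino acid biosynthesis genes were lower in the deletion, 7 were higher and 7 did not pass; adjusted over the list alone, 72 were lower and 8 higher. The mean log2 change was -1.85, a 3.60-fold fall (camera, adjusted p = 2.34e-20). With an estimated correlation the list was not called (adjusted p = 0.137). Fry, which asks whether its genes moved one way and not whether they moved more than other genes, gave adjusted p = 4.3e-08. With 70.4% of all genes called, a fry call does not show that a list stands out. None of the 15 lists called with the preset correlation was called with an estimated one. The list of 86 also holds genes that do not encode enzymes of synthesis, named here after their values were seen. The regulator genes metJ (-1.08), tyrR (-1.08), cysB (-0.69), glnL (-1.52), glnG (-1.31) and, in the branched-chain list, ilvY (-0.78) were lower. Of other regulator genes trpR (0.39) and glnB (0.29) were higher and argR (0.02) did not pass. The sulfate transport genes cysP, cysT and cysW were lower.

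Members that moved against the rest of their list were named after their values were seen. In threonine and lysine synthesis dapB (0.95) and dapD (0.23) were higher. In aromatic synthesis aroK (0.31) and the repressor gene trpR (0.39) were higher, and in the serine to asparagine group serC (0.90), asnB at SO_3175 (0.48) and the regulator gene glnB (0.29). In methionine, cysteine and sulfate assimilation cysQ at SO_0191 (-0.12) and cysE (-0.09) did not pass the test, while cysQ at SO_1655 was lower (-0.62). In arginine synthesis neither argR (0.02) nor carB (-0.15) passed. Outside amino acid synthesis hslO (0.64), rpoH (0.31) and clpP (0.12) were higher among the chaperones and heat-shock proteases, and pepN (SO_2600, 0.33) and clpP among the peptidases. In the TCA cycle list lpdA (0.51), aceF (0.32), sucD (0.26) and sucC (0.20) were higher. SO_1520 (0.36) was higher in lactate utilization and fadD (0.13) in fatty acid degradation, and pyrH (-0.26) lower in nucleotide biosynthesis.

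**Figure D2:**
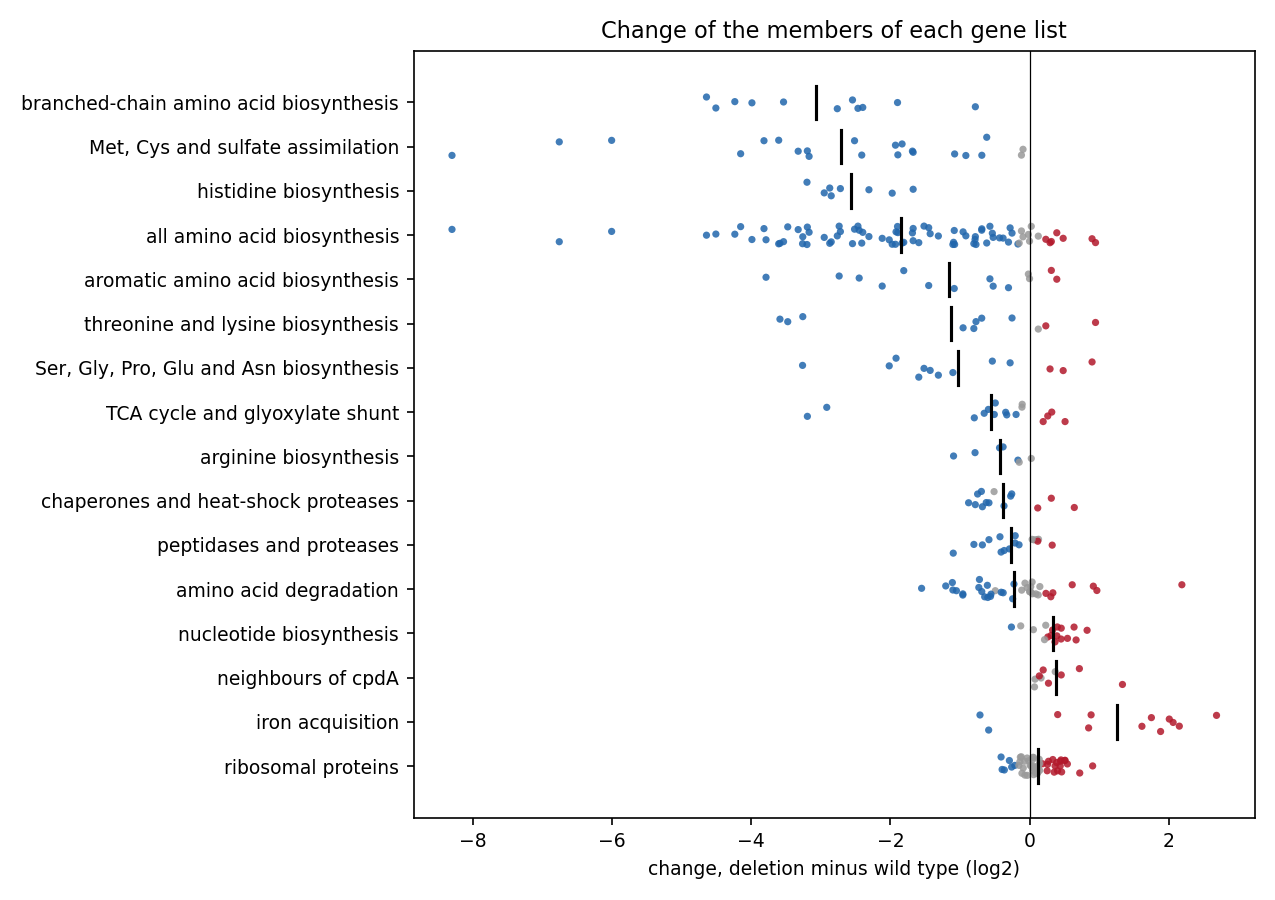
Each point is the log2 change of 1 gene in the cpdA deletion, in the 15 lists called with the preset correlation and in ribosomal proteins, which were not called. Blue and red points passed the single-gene test as lower or higher, grey points did not, and black bars mark the mean of each list. Amino acid biosynthesis lists lie to the left, with means from -3.07 to -0.43, and iron acquisition to the right with a mean of 1.25; the mean of ribosomal proteins, 0.12, was -0.000152 with quantile normalization.

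Genes for amino acid degradation moved both ways. Of 39, 19 were lower, 7 higher and 13 did not pass, over all genes and adjusted over the list alone. The lowest values in the list were those of SO_1677 (-1.55), SO_1895 (-1.20) and SO_1898 (-1.11). The hppD gene, of 4-hydroxyphenylpyruvate dioxygenase in tyrosine degradation, was 4.56-fold higher (adjusted p = 5.91e-10), or 2.86-fold with normexp. The list was called lower by a narrow margin (mean -0.23, adjusted p = 0.0451). With an estimated correlation it was not called (adjusted p = 0.608), nor without deletion replicate 1 (mean -0.17, adjusted p = 0.118) or without wild-type replicate 1 (mean -0.21, adjusted p = 0.0517). It also lost its call with normexp (adjusted p = 0.0638), quantile normalization (0.0563), array weights (0.0964) and the replicate number as a block (0.0508). Amino acid transport genes, 3 higher, 3 lower and 2 not passing, were not called as a list (adjusted p = 0.85). Of these potE rose by 0.47, which normexp reduced to 0.22 (adjusted p = 0.11), mtr rose by 0.25, and aspT fell by 0.34.

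Peptidases and proteases had 11 of 17 genes lower and 2 higher (mean -0.26, adjusted p = 0.043; adjusted p = 0.203 with an estimated correlation), with ggt (SO_1952) at -1.10 and prlC at -0.80. That call was lost without wild-type replicate 1 (adjusted p = 0.0502) or deletion replicate 1 (0.0755). Chaperones and heat-shock proteases had 10 of 14 genes lower and 3 higher (mean -0.38, adjusted p = 0.0192; adjusted p = 0.203 with an estimated correlation), with htpG at -0.88, dnaJ at -0.78, clpB at -0.75 and hslU at -0.69. Of 20 aminoacyl-tRNA synthetase genes 10 were lower and 2 higher, and the list was not called (adjusted p = 0.0926; 0.0336 with quantile normalization). The largest of these falls were alaS (-0.40) and cysS (-0.40).

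The malate synthase gene aceB was 9.14-fold lower (log2 -3.19, SE 0.07, adjusted p = 1.25e-10) and the isocitrate lyase gene aceA 7.54-fold lower, while sdhA and sdhC, of succinate dehydrogenase, fell by 0.79 and 0.65. The list of TCA cycle and glyoxylate shunt genes had 10 of 16 lower and 4 higher (mean -0.56, adjusted p = 0.0254, or 0.345 with an estimated correlation). It also holds the propionate genes prpF, acnD, prpC and prpB and the pyruvate dehydrogenase genes aceE, aceF and lpdA, named after their values were seen. Of these, acnD (-0.33), prpC (-0.59), prpB (-0.51) and aceE (-0.19) were lower, aceF (0.32) and lpdA (0.51) higher, and prpF (-0.11) did not pass. The acetyl-CoA synthetase gene acs was 18.9-fold lower (log2 -4.24, SE 0.07, adjusted p = 8.8e-12), and pta, of phosphate acetyltransferase, 3.99-fold higher (adjusted p = 1.08e-09). The aldehyde dehydrogenase gene exaC was 19.9-fold lower, and yiaY, an alcohol dehydrogenase gene, 4.01-fold higher. Of the 5 lactate utilization genes 4 were lower, SO_1522 (-0.89), SO_1519 (-0.66), SO_1518 (-0.53) and SO_1521 (-0.44), and 1 higher; the list was not called (adjusted p = 0.207). Fatty acid degradation had 5 of 7 genes lower and 1 higher (2 adjusted over the list alone), led by fadB (-0.73) and fadI (-0.62), and was not called (adjusted p = 0.0804; called lower with the brightest probe, adjusted p = 0.0377).

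Genes for iron acquisition were higher. Of 12, 10 were higher and 2 lower, with a mean log2 change of 1.25 (adjusted p = 0.0214; adjusted p = 0.345 with an estimated correlation). The heme utilization genes hutZ and hutX rose 6.44-fold and 4.45-fold (adjusted p = 2.69e-06 and 1.04e-05), and SO_3030 and SO_3033 of the siderophore cluster 4.18-fold and 4.02-fold. The 2 lower members were the bacterioferritin genes bfr at SO_1111 (-0.59) and SO_1112 (-0.71), while the ferritin gene ftnA rose by 0.85 (adjusted p = 8.68e-08). Ferritins and bacterioferritins store iron, and these 3 genes were named after their values were seen. The wild-type arrays spread widely for hutZ, with an SD of 0.58 against 0.10 in the deletion. Nucleotide biosynthesis genes rose as well, 12 of 17 higher and 1 lower (mean 0.34, adjusted p = 0.0169; adjusted p = 0.345 with an estimated correlation), with pyrD at 0.83, guaB at 0.67, guaA at 0.64 and purB at 0.55.

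Among genes with a symbol the largest rise was that of ushA, of a periplasmic nucleotidase, at 10.7-fold (log2 3.42, SE 0.04, adjusted p = 1.54e-12). The deoxyribose-phosphate aldolase gene deoC rose 4.28-fold and the purine nucleoside phosphorylase gene deoD (SO_1221) 3.67-fold. The organic hydroperoxide resistance gene ohr rose 4.12-fold and ccpA, of a cytochrome c peroxidase, 3.69-fold. The pdsO gene rose 6.22-fold (3.63-fold with normexp) and tsgA 3.65-fold. Among the falls, thiC, of thiamine synthesis, was 20.4-fold lower (log2 -4.35, SE 0.15, adjusted p = 2.12e-09).

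**Figure D3:**
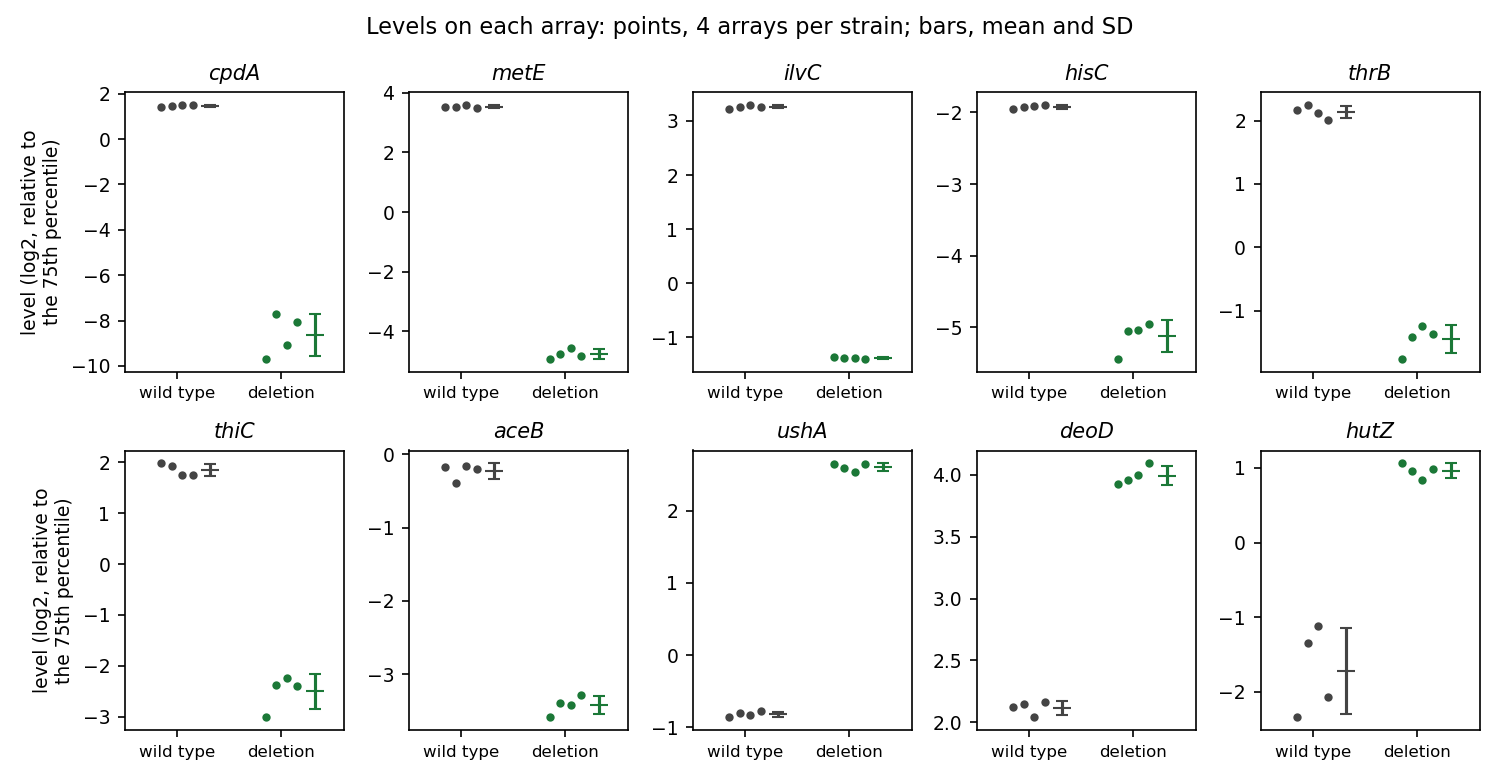
Points are the levels of 10 genes on each array (log2, relative to the array's 75th percentile; 4 arrays per strain), and the bars beside them give the mean and SD. The vertical scale differs between genes and does not start at 0. In all 10 genes the 4 deletion arrays lie apart from the 4 wild-type arrays, and hutZ has the widest wild-type spread of these (SD 0.58).

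Of 15 genes for aerobic terminal oxidases 6 were higher and 0 lower, cydX by 1.15, cydB by 0.99, SO_4609 by 0.81 and SO_3286 by 0.77, and the list was not called (mean 0.30, adjusted p = 0.0804). The metal reduction list, of cytochromes and proteins that work with them, had 4 of 9 genes higher and 1 lower (adjusted p = 0.657). SO_1776, which does not encode a cytochrome, rose by 0.89, and mtrC, of an outer-membrane decahaem cytochrome, fell by 0.27. The other anaerobic respiration list had 3 of 20 higher and 6 lower, or 2 and 4 adjusted over the list alone (adjusted p = 0.349). In it fccA, of the periplasmic fumarate reductase, rose by 0.77 and napA, of periplasmic nitrate reductase, fell by 0.77. The napA values of the strains overlapped, with an SD of 0.52 over the wild-type arrays. ATP synthase had 4 of 7 genes higher and 0 lower, or 2 and 0 adjusted over the list alone (adjusted p = 0.305). The largest of these was atpD (0.36). The calls of the other 3, atpA, atpB and atpE, were lost with quantile normalization (adjusted p = 0.512, 0.463 and 0.119). Those of atpA and atpE were also lost with the brightest probe (0.422 and 0.0926). That of atpB was lost with no filter on dim probes (0.0503) and with the scan run as a random block (0.0505). With the replicate number as a block, atpA (0.0551) and atpB (0.0732) lost theirs. Without 1 array, atpA lost its call in 5 of 8 fits, atpB in 7 and atpE in 3.

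Ribosomal protein genes, 54 in all, had 18 higher, 6 lower and 30 not passing, and were not called (mean 0.12, adjusted p = 0.236). The mean was -0.000152 with quantile normalization, the only alternative that changed the direction of this list. That setting gives all arrays the same distribution of values, which can remove a shift shared by bright genes. The direction of the list thus depends on the scaling of the arrays. The largest rises were rpmH (0.91) and rpsF (0.72). Flagella and chemotaxis genes had 9 of 36 higher and 13 lower (mean -0.01, adjusted p = 0.595), with motY at 0.95 and flgH at -0.64. Fatty acid biosynthesis had 4 of 9 higher and 4 lower (adjusted p = 0.85), with fabZ at -0.57 and fabF at 0.50; its mean was -0.04 and its median 0.10. Of 5 cyclic dinucleotide genes 2 were lower and 0 higher (adjusted p = 0.205), with changes of -1.22 for mxdA and -0.23 for csrD.

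Of the 3 prophage regions none was called as a list by camera. In MuSo1, 7 of 41 genes were higher and 19 lower (adjusted p = 0.0926), and in MuSo2, 14 of 53 were higher and 7 lower, or 11 and 7 adjusted over the list alone (adjusted p = 0.657). In LambdaSo, 27 of 75 genes were higher and 39 lower (adjusted p = 0.349). Its mean was 0.07 and its median -0.19, and fry, which called it (adjusted p = 0.0103), put its direction as higher where camera put it as lower. SO_2998 was 3.10-fold higher and SO_3003 2.81-fold higher. The mean and median also differed in sign for amino acid transport (0.01 and -0.06) and for the metal reduction list (0.12 and -0.02). For the lists with no second count given, the counts adjusted over the list alone equalled those over all genes.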

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

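Both tests for deletion replicate 1 were chosen after that array had been seen to stand apart, with their predictions written before the tests were run. In each strain, a value was looked at again when its gap to the nearest other array took up most of the range of the 4 arrays (Dixon's test). Of 276 sets of 4 values, 22 met this (7.97%), where chance gives about 1 in 20. Deletion replicate 1 held 15 of these 22, deletion replicate 3 held 3, deletion replicates 2 and 4 held 0, and the wild-type arrays held 4.

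The brightness of deletion replicate 1 stood apart: its 75th percentile was 4630, against a mean of 2863 for the other 3 deletion arrays. Of amino acid synthesis genes, 5 were picked out in it, all as the lowest deletion value. Their levels (mean of the other 3 deletion arrays in brackets) were -4.44 for metH (-4.02), -5.37 for trpD (-4.29), -2.52 for trpB (-1.71), -5.39 for hisD (-5.07) and -4.78 for hisH (-4.17). Of the named synthesis genes not picked out, deletion replicate 1 also held the lowest deletion value of most. Examples are metE (-4.93), metB (-5.22), ilvG (-4.69), thrA (-2.39) and hisC (-5.44). Among these genes it held the highest deletion value of ilvC (-1.36), tyrA (-3.14), argC (-2.40) and glyA (1.95) alone. Outside amino acid synthesis it was picked out as lowest for SO_3896 at 4.98 (5.28), ggt (SO_1952) at -1.22 (-0.98), SO_1518 at -1.05 (-0.40), napA at -2.31 (-1.67), SO_3033 at 0.13 (0.89), guaB at -0.24 (0.08), fadI at -2.25 (-1.88) and SO_0646 at -6.02 (-5.34), and as highest for lon at 0.60 (0.52). Deletion replicate 3 was lowest for SO_3898 at -0.56 (0.49), guaA at -0.83 (-0.66) and fabA at -0.56 (-0.26). Among the wild-type arrays, replicate 4 was lowest for SO_3898 at -0.77 (0.07), replicate 3 lowest for rpsU at 2.83 (3.02), and replicate 1 highest for SO_1895 at -3.55 (-3.69) and SO_0646 at -4.88 (-5.01).

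The distance of deletion replicate 1 from the other deletion arrays had an SD of 0.209 over genes, against 0.106, 0.15 and 0.162 for replicates 2, 3 and 4 taken the same way. A response tied to signal level, as a brighter array might give, is argued against: subtracting the median distance of genes at matched signal left 99.6% of the SD. A larger change of the same genes in this sample stays open. Its distance correlated over genes with the change of the other 3 deletion arrays at 0.113. Taken the same way, replicates 2, 3 and 4 gave -0.185, -0.188 and -0.070. The mean of the other arrays enters both values with opposite sign, which pulls such a correlation down. The amino acid biosynthesis list lay at a median of -0.14 from the other deletion arrays, against 0.05, 0.08 and 0.06 for replicates 2, 3 and 4. The handling of this sample before hybridisation was not tested. Without it, 3470 genes were called, and the amino acid biosynthesis list had a mean of -1.80.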

How the results depend on the processing

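All alternatives were listed before the data were examined, with median in place of mean spot signals for normexp put in afterwards. The counts of changed genes stayed within 1.5 times their main values under every alternative: 3063 to 3826 genes with other processing and 3117 to 3470 without 1 array, against 3343. Changes of at least 2-fold numbered 149 to 191 higher and 165 to 207 lower with other processing. Leaving out saturated probes moved nothing, since no spot was saturated. The change of cpdA lay between -10.09 and -6.85 with other processing, the smallest with normexp, and between -10.40 and -9.74 without 1 array; asking for signal on all 8 arrays left cpdA without a probe and so without a value. Normexp moved the folds of 8 further named genes by over 1.5 times, all toward 0: metE (-7.62), metB (-5.99), metF (-5.40), hisB (-2.27), hisC (-2.53), hisD (-2.15), hppD (1.52) and pdsO (1.86).

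The amino acid biosynthesis list kept its call under each alternative but 1, at a mean of -1.85 to -1.68, and of -1.87 to -1.80 without 1 array. With an estimated correlation its mean of -1.85 had an adjusted p of 0.137, while its adjusted p under the other alternatives was at most 4.3e-08. The amino acid degradation list lost its call with an estimated correlation (mean -0.23, adjusted p = 0.608), normexp (-0.16) and quantile normalization (-0.19). The same held for array weights (-0.18) and the replicate number as a block (-0.23). Its mean ran from -0.25 to -0.17 without 1 array, with the call lost without wild-type replicate 1 or deletion replicate 1. The cause was not tested. Of 682 gene list results under alternatives, 642 kept direction and side of the threshold, 27 lost a call, 8 gained one and 5 changed direction. The direction meant is that of the list test, which can differ from the sign of the mean. With fry it changed for flagella and chemotaxis (mean -0.00753) and LambdaSo (0.0652), whose means stayed as in the main analysis. Amino acid transport, with a main mean of 0.0117 but a lower direction, changed with quantile normalization (0.0539) and the brightest probe (0.0921). Ribosomal proteins changed with quantile normalization (-0.000152). The 8 gained calls were aminoacyl-tRNA synthetases with quantile normalization, fatty acid degradation with the brightest probe, and with fry these 2 lists, cyclic AMP signalling, lactate utilization, aerobic terminal oxidases and cyclic dinucleotides. None of the 4 lists that changed direction was called in the main analysis, and under these alternatives LambdaSo alone was, by fry (adjusted p = 0.0103). Of 2739 results of named genes, 2684 kept both, 40 lost a call, 12 gained one and 3 changed direction: tolC (-0.000557) and SO_3906 (-0.0406) with quantile normalization and SO_3906 with the brightest probe (-0.0536), neither of them called.

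The strains share the replicate numbers 1 to 4 in the labels. Same-numbered arrays did not deviate together: the correlations over genes of their deviations from the strain means were -0.18, 0.16, -0.03 and -0.13, and replicate 2 alone correlated best with its own number. With the replicate block 3212 genes were called, and the amino acid degradation list (mean -0.23) had an adjusted p of 0.0508; atpA and atpB lost their calls. With the scan run as a random block (consensus correlation 0.00854) 3320 genes were called. The run of the wild type and the strain cannot be told apart. Of 35 splits of the 8 arrays into 4 and 4, the real one alone, 1 split, gave as many as 3343 genes. The highest of the others gave 0 with limma (402 at an unadjusted p under 0.05, against 3462). Chance assignment of arrays is thus unlikely, at 1 of 35 splits, but not excluded. The other splits mix the strains, which adds the strain difference to their residual spread, so few calls were to be had there. A difference between runs that follows the strain would give the same result. On deletion replicate 4, the array with the lowest share, 97.8% of the non-control spots were well above background, so signal limits few genes.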

Other observations

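The tests of matched signal and of scan runs for the amino acid genes, both tests of the iron genes and the test of neighbouring genes were chosen after the results were seen; the probe test was written down before. The iron tests were first run on 15 genes picked from the runs of neighbours and were then moved to the list fixed earlier. A further test, of other scalings of the arrays for the amino acid genes, was run and dropped. It argued against scaling, but its values are not given here and no conclusion is drawn from it. The genes below without a symbol, and others outside the naming rule, were also chosen after their values were seen.

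Some of the large changes lay in blocks of neighbouring genes, several of them outside the lists. The thiamine synthesis block from SO_2440 to SO_2445, with thiH, thiS, thiE and thiC, was lower throughout, with a mean log2 change of -3.61 over 6 genes. A block of 10 genes from SO_0100 to SO_0109, with the formate dehydrogenase genes fdnG and fdxH and the selenocysteine genes selA and selB, had a mean of -1.83. The 5 genes from SO_2854 to SO_2858, which have no symbol, had a mean of -3.40, with SO_2857 27.6-fold lower. In the other direction, the block with deoC, deoA and deoD (SO_1217 to SO_1221) had a mean of 1.71, the block from hutZ and hutX to SO_3676 a mean of 2.41 over 10 genes, and the block of 4 that ends with greA (SO_1188 to SO_1191) a mean of 1.32. Every gene of these blocks passed the limma test.

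Within the LambdaSo prophage region, 10 consecutive genes from SO_2997 to SO_3006 were all higher, with a mean of 1.38. Of the other 65 genes of the region 39 were lower and 17 higher, with a median of -0.31. The region therefore did not move as 1 unit.

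A hypothesis from these blocks is that genes next to each other, as in operons, changed together. Of 369 genes on numbered chromosomal tags changed at least 2-fold, 123 lay in 20 runs of 4 or more neighbours that moved one way, 15 runs lower and 5 higher. In 10000 random gene orders the highest number of genes in such runs was 8. This may reflect shared transcripts, which were not measured here, and a run counts neighbours in tag order without regard to strand. In 1 of the 123 genes, malQ, 2 of the 3 kept probes were not well above background on any deletion array, so its change is not exact.

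The lower level of amino acid biosynthesis genes was weighed against technical explanations. A bias tied to signal level is argued against: the median of the list was -1.68, while 10000 random lists matched on signal had medians from -0.17 to 0.25. Among the 72 lower genes, all with 2 or 3 kept probes, 0% had a probe that was not lower. A fall carried by 1 stray or damaged probe, with another probe not lower, is thus argued against. The genes were picked by the mean of these same probes and only the sign was asked. Weaker disagreement between probes is therefore not excluded. A difference between scan runs cannot be told apart from the strain, because run 1 holds the wild type alone; between runs 3 and 2, both of the deletion, 0 of the 72 genes differed by 2-fold or more. The deletion itself, and any difference in growth between the cultures, stay open and untested.

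Iron acquisition genes differed between the wild-type arrays themselves. The mean level of the 12 genes was -1.08, -0.62, -0.52 and -0.95 on wild-type replicates 1 to 4 and 0.28, 0.52, 0.51 and 0.52 on deletion replicates 1 to 4. The median SD was 0.425 in the wild type and 0.146 in the deletion. Noise at these signal levels is argued against, since the highest median SD of 10000 lists matched on signal was 0.113. Removing each array's median deviation at matched signal left 102.5% of the spread, so no shift shared by genes of similar signal accounted for it. That value cannot decide on the scaling of whole arrays, because the values had already been scaled array by array. Wild-type replicates 1 and 4 also lay apart from 2 and 3 in genes outside the list, picked after their values were seen. On replicates 1 to 4 napA lay at -1.37, -0.56, -0.67 and -1.62, and mtrC, the other way, at 2.04, 1.74, 1.78 and 2.10. A candidate explanation is that iron supply or the point of harvest differed between wild-type cultures. The labels give no measure of either, and it was not tested. The higher level of the iron list in the deletion held without any 1 array, at a mean change of 1.15 to 1.34.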
